A study of Rattus norvegicus with 6 samples.

How the data were processed

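Penile tissue of adult male Sprague-Dawley rats was profiled 12 weeks after surgery on 1-colour Agilent rat expression arrays. Each array carried the RNA of 1 rat, and the labels placed 3 rats in the sham-operated group and 3 in the group with bilateral resection of the cavernous nerve (CN), the nerve that carries the autonomic supply of the erectile tissue. Per the labels' protocols, RNA was isolated with TRI Reagent and labelled directly with the Universal Linkage System, so that no amplification step is named.

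The deposited scanner files hold a background-subtracted spot intensity on a linear scale, detrended within each array by Feature Extraction 10.7.3.1 per the file headers, together with raw median spot and background intensities and quality marks for each spot. No normalization between arrays was applied to these deposited intensity values, per the file headers. The deposited value table holds linear intensity as well: between 99.76% and 99.80% of its values lay within 1% of the scanner value of the same probe, and 7.75% to 16.2% of its cells were blank, those of probes not well above background. Its column medians were 11791, 12588.5 and 12022.5 for sham rats 1 to 3 and 14168.7, 12391.8 and 11550 for CN resection rats 1 to 3, so no scaling to a common median was visible in it. The submitters' processing notes name RMA without a role or version, and which values it was applied to is not given in the sources used here.

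Each array held 45018 spots, of which 43379 were not controls. They carried 41012 probes, 263 of them with 10 spots each. Control spots were left out, as were spots that Feature Extraction marked as non-uniform or as population outliers, and the remaining spots of a probe were averaged. No non-control spot was saturated on any of the 6 arrays. The values analysed were log2 intensity minus the array's 75th percentile of log2 intensity, so that 0 is that percentile on every array. Levels of different probes were not set against each other, since probes differ in how strongly they bind.

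A probe entered the analysis if it was well above background on at least 3 of the 6 arrays, whatever their group, which left 36746 probes. Probes were named by matching their unversioned accession to a RefSeq gene table of the GRCr8 rat assembly, used for names only; the array's own design was built on the older rn4 assembly, and no coordinates are reported. A symbol was found for 16336 probes (13031 symbols), and the other 24676 probes kept the accession in the file and are called unmatched accessions. A gene was represented by its probe with the highest mean over all 6 arrays. After this step 32610 genes or unmatched accessions remained, and the 32501 with values on at least 2 arrays of each group were tested, 12311 of them with a symbol. A gene whose brightest probe was marked as an outlier on most arrays of a group was therefore not tested. All are called genes in what follows. Different probes of a gene often disagreed: over 1946 genes with 2 probes, the Spearman correlation of their changes after CN resection was 0.10 across genes, which are not independent replicates, with a bootstrap interval of 0.06 to 0.15 over 1000 draws. Among the 27 of these genes whose probes both varied most over the arrays, it was 0.58.

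CN resection was compared with sham in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, group only, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Before the data were examined, 34 lists were fixed, with 887 entries in all. They covered smooth muscle, endothelial, fibroblast, Schwann cell, neuronal, macrophage, lymphocyte, mast cell, skeletal muscle, squamous epithelial, urothelial, adipocyte, cartilage and bone, and red blood cell markers. The pathway lists covered nitric oxide and cGMP signalling, relaxant receptors, RhoA and contractile receptors, TGF-beta, collagens and matrix, metalloproteases, hedgehog signalling, neurotrophic factors, muscle denervation, apoptosis, inflammation, interferon, hypoxia, oxidative stress, mitochondrial respiration, androgen signalling and cell cycle. Ribosomal protein, immediate early and heat shock genes served as signs of RNA and tissue handling. Each list with at least 5 genes measured on all 6 arrays was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists; camera with an estimated correlation and fry were run beside it.

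The named genes were set by a rule written before the data were examined. It takes the 12 genes with a symbol that changed most in each direction among those passing; where fewer than 5 pass, it takes the 10 with the smallest p in that direction among genes above background on all 6 arrays, stated as not passing. It adds genes above background on all 3 arrays of 1 group and none of the other, up to 4 members with the smallest p from each list described, and 24 genes of erectile physiology, fibrosis and nerve whatever their values. Of these 24, 20 were measured here under a matched symbol; Acta2, Myh11 and Rock1 are among those not analysed here. Some genes that the rule names are not reported here.

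The gene and list tests were tested on simulated data built from the spread of these arrays. With 32501 genes, the gene test recovered 69 of 100 genes planted at a log2 change of 1 and 87 of 100 planted at 2, and called 9 of 32301 unchanged genes. All these genes were planted at once, which eases the adjusted threshold. The counts therefore do not show how often a gene would be recovered if only a few changed. A list planted at a mean log2 change of 0.3 was called, and 0 of the 33 other lists were. Genes were drawn independently of each other, and for the list test the largest spreads were capped. The 0 therefore does not show how often camera calls an unchanged list whose genes move together. On the real arrays the estimated inter-gene correlation reached 0.66, for ribosomal protein genes. The number of arrays limits the precision: the median standard error of a log2 change was 0.11.

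The 3 sham arrays lay on 1 slide and the 3 CN resection arrays on another, so slide and group cannot be told apart. Alternatives fixed before the data were examined changed the background correction (normexp with an offset of 50, on median spot signals because mean signals were not among the columns used here), the scaling, the filter on dim probes, the rule for a gene's probes, the test, the threshold and the set test, used the deposited value table, or left out each rat in turn. The planned average of a gene's probes took whichever probes had a value on an array. After its result was seen, a version that averaged the same probes on every array was added beside it. Alternatives that kept marked spots, left out a corner of 1 array or left out the 2 arrays farthest from the others were added after seeing the data.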

Results

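The arrays measured transcript levels in the penile tissue of 6 rats, 3 sham-operated and 3 with both CNs resected, 12 weeks after surgery. The comparison between the groups asks which transcripts of the erectile tissue differ 12 weeks after resection of these nerves. Whether the tissue still lacked its nerve supply then was not measured in the data used here. Between 83.8% and 92.2% of the 41012 probes were well above background on an array, with 36165, 37832 and 36500 probes on sham arrays 1 to 3 and 34363, 37251 and 36191 on CN resection arrays 1 to 3. Arrays of the same group correlated at 0.975 to 0.996 across genes and arrays of different groups at 0.960 to 0.995, so the groups did not form separate clusters. The lowest correlation, 0.960, was between sham array 2 and CN resection array 3, which lay at opposite ends of the first principal component (55.6% of the variance). The SD of the log2 difference between a pair of arrays ran from 0.20 to 0.61.

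No gene passed the test for a change after CN resection. Of 32501 genes, 0 were higher and 0 were lower at a limma adjusted p under 0.05, 0 passed at 0.10, and the lowest adjusted p was 0.903. At an unadjusted p under 0.05 there were 1707 genes, 1097 higher and 610 lower, where 1625.1 would be reached with no change at all. The same model without eBayes moderation also called 0 genes, with 2115 at an unadjusted p under 0.05. Averaging whichever probes of a gene had a value called 7 genes (lowest limma adjusted p = 0.00173): Ap2a2, Fut2, Nes, Plxdc1, Rgr, Slc8a1 and the unmatched accession NM_001105984. For all 7 the probes averaged differed between arrays, and with the same probes on every array 0 genes were called and the largest of their log2 differences was 0.16 in size. For 30339 genes, 93.3% of those tested, the 95% interval of the change lay inside 2-fold in both directions. This bounds the signal of the probe read, from which a difference between the slides cannot be taken out. Other probes of the same gene often disagreed. The groups did not overlap for 3679 of 31568 genes with values on all arrays, or 11.7%, where chance gives 10% for 3 arrays against 3.

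The nitric oxide and cGMP pathway, which relaxes cavernous smooth muscle during erection, showed no gene past the test. Nos1, the neuronal nitric oxide synthase, had a log2 signal of −2.14 ± 0.05 (SD, n = 3) in sham rats and −1.97 ± 0.13 (SD, n = 3) after CN resection. Its log2 difference of 0.18 had a 95% interval from −0.04 to 0.39 (limma adjusted p = 0.903). Nos3, the endothelial synthase, differed by 0.12 (−0.11 to 0.36) and Pde5a, the cGMP phosphodiesterase that sildenafil inhibits, by 0.11 (−0.51 to 0.73). The soluble guanylate cyclase subunits Gucy1a1 and Gucy1b1, formerly Gucy1a3 and Gucy1b3, differed by −0.11 and 0.12, and Prkg1, the cGMP-dependent protein kinase, by −0.31 with a wide interval from −1.20 to 0.57. Of the 23 measured genes of the list, 14 were higher and 9 lower with a median log2 change of 0.06 (camera adjusted p = 0.874), and 0 passed adjusted over the list alone. Npr1, a natriuretic peptide receptor that makes cGMP, had the smallest p of the list and a log2 difference of −0.20. Relaxant receptors and channels (12 higher, 12 lower; camera adjusted p = 0.675) and the RhoA and contractile receptor list (11 higher, 12 lower; camera adjusted p = 0.576) did not pass either. Rhoa and Rock2, whose products keep smooth muscle contracted, differed by −0.26 (−0.65 to 0.13) and 0.14 (−0.10 to 0.38), and Edn1, the vasoconstrictor endothelin 1, by −0.04 (−0.43 to 0.34).

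**Figure D1:**
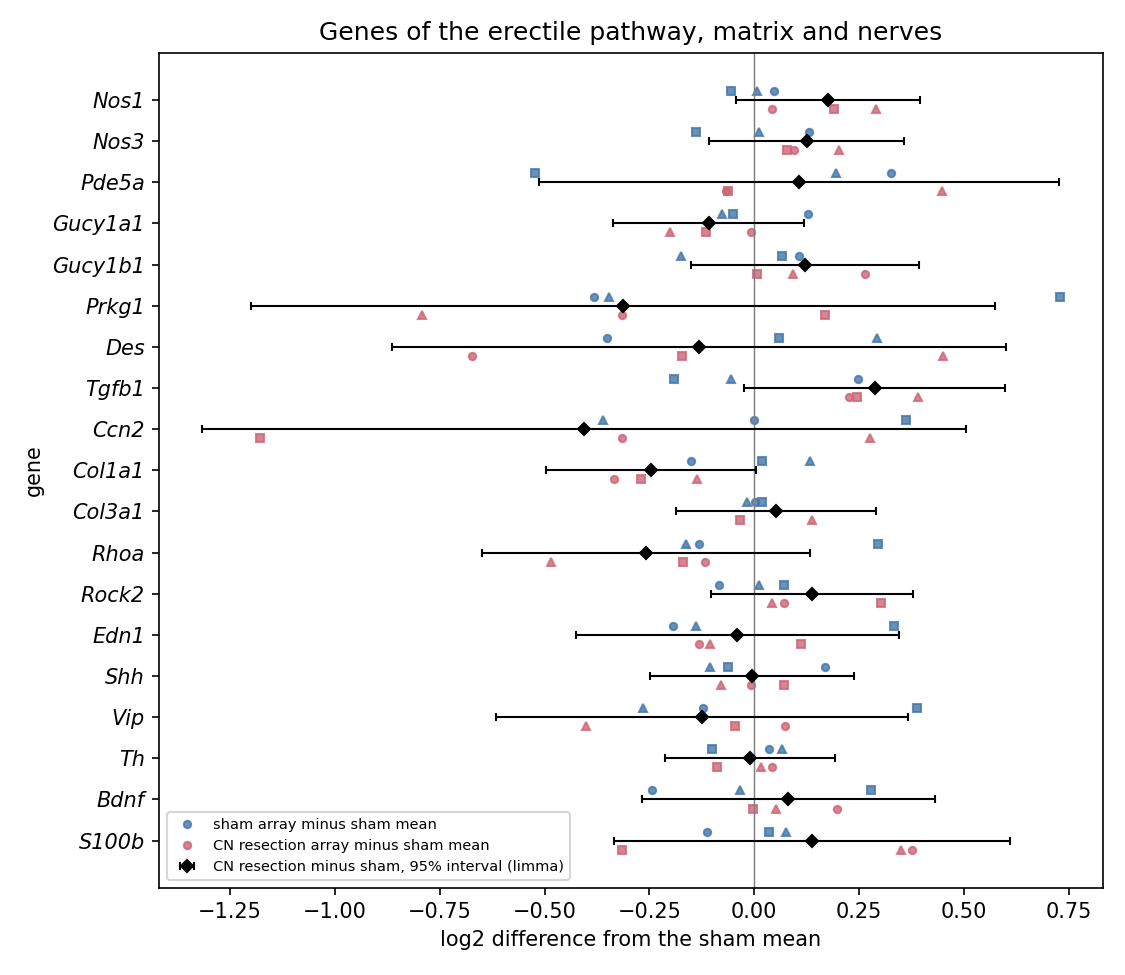
Log2 difference between CN resection and sham for 19 of the genes named whatever their values, with the 95% interval from limma as a black bar and each array as a coloured point set against the sham mean (circle, square and triangle for rats 1, 2 and 3). The interval includes 0 for every gene drawn, and no gene passed the adjusted test.

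Collagen and matrix genes were lower as a list by a small amount. Of 19 measured members, 6 were higher and 13 lower, with a median log2 change of −0.09 over the 18 members in the test (camera adjusted p = 0.021). The call was lost with an estimated correlation (adjusted p = 0.909 with an estimated correlation) and with quantile normalization, where the mean change was −0.01 (adjusted p = 0.427). Every list tested lay between 0.909 and 0.936 with an estimated correlation, so that loss does not single out this list. It was also lost with normexp, where the mean change was −0.047 (adjusted p = 0.0533), and with the replicate number as a block (adjusted p = 0.0697). The members with the smallest p were P4ha1, a collagen prolyl hydroxylase, at −0.39 ± 0.10 (SE), Serpinh1, a collagen chaperone, at −0.30 ± 0.10, Col4a1, a basement membrane collagen, at −0.27 ± 0.10, and Col1a1, the main fibrillar collagen chain, at −0.25 ± 0.10. Col3a1, the second large fibrillar collagen, differed by 0.05 (−0.19 to 0.29). No member passed over all genes tested or adjusted over the list alone. Serpinh1, Col4a1 and Col1a1 were read by probes among the brightest 5%. Among the brightest 1% of genes, 314 of 325 (96.6%) were lower after CN resection, with a median log2 change of −0.21, against 44.0% lower over all genes. The medians of the list's levels were −0.13 ± 0.11 (SD, n = 3) in sham rats and −0.15 ± 0.13 (SD, n = 3) after CN resection. Each array's median is the level of whichever member lay in the middle there, so these medians do not measure the change. The call ended without sham rat 3 (adjusted p = 0.286) and without CN resection rat 2 (adjusted p = 0.400), and over all alternatives the adjusted p ran from 0.00153 to 0.909.

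**Figure D2:**
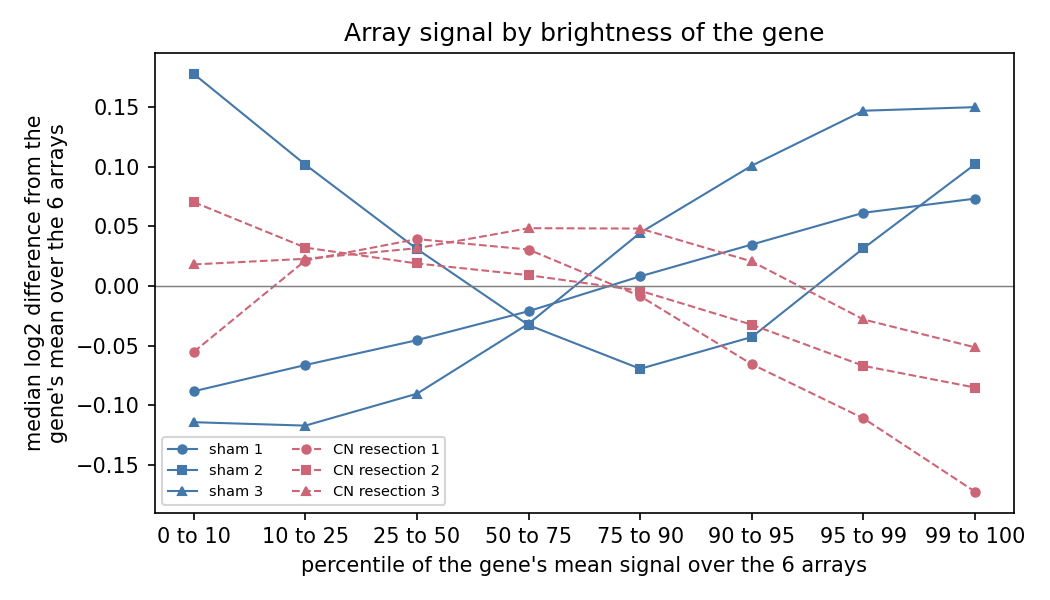
Median log2 difference of each array from the mean of the 6 arrays, for genes grouped by the percentile of their mean signal; blue lines are sham arrays and red dashed lines CN resection arrays. In the brightest 1% the 3 sham arrays lie between 0.07 and 0.15 and the 3 CN resection arrays between −0.17 and −0.05.

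No list of profibrotic or proteolytic genes passed the list test. Tgfb1, the central profibrotic cytokine, was at −3.31 ± 0.22 (SD, n = 3) in sham rats and −3.02 ± 0.09 (SD, n = 3) after CN resection, a log2 difference of 0.29 (−0.02 to 0.60; limma adjusted p = 0.903). Ccn2, formerly Ctgf, a matrix-associated growth factor, differed by −0.41 with an interval from −1.32 to 0.50. The TGF-beta and BMP list had 13 members higher and 15 lower (camera adjusted p = 0.811). Of 24 metalloproteases and inhibitors, 12 were higher and 12 lower (camera adjusted p = 0.869). In this list 1 member, Mmp23, passed adjusted over the list alone (adjusted p = 0.0291) but not over all genes: it was higher on all 3 CN resection arrays than on any sham array, by 0.57 ± 0.10 (SE). Mmp3, a stromelysin, differed by −0.68 and Adamts9, a secreted protease, by 0.93, neither passing. Adamts9 was not well above background on every array. Hedgehog genes (4 higher, 6 lower; camera adjusted p = 0.874) did not pass, and Shh differed by −0.01 (−0.25 to 0.24).

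Nerve and Schwann cell transcripts gave no call 12 weeks after the nerve had been cut. The lack of a call does not show that the nerve content of the tissue was unchanged. How far these transcripts follow nerve content was not tested. A signal above background also does not by itself show the named transcript on these arrays. S100b, a Schwann cell marker, had a log2 difference of 0.14 (−0.34 to 0.61). Of 21 measured genes of the Schwann cell list, 9 were higher and 12 lower (camera adjusted p = 0.396); Cldn19 and Sox10, both read by probes among the brightest 5%, differed by −0.19 and −0.26. Vip, a relaxant neuropeptide, and Th, an enzyme of catecholamine synthesis, differed by −0.12 (−0.62 to 0.37) and −0.01 (−0.21 to 0.19). In the neuronal list 9 genes were higher and 16 lower (camera adjusted p = 0.609). Tac1, the precursor of substance P, differed by 0.50 ± 0.13 (SE), and Calca, the precursor of calcitonin gene-related peptide, by −0.28 ± 0.08, neither passing. The neurotrophic and Schwann repair list had 16 of 23 genes higher, with a median log2 change of 0.07 (camera adjusted p = 0.396; fry adjusted p = 0.055). Its members with the smallest p were Ntrk2, the receptor of brain-derived neurotrophic factor, at 0.33 ± 0.08 (SE), and Sox2, a transcription factor of immature Schwann cells, at 0.48 ± 0.13. Bdnf itself differed by 0.08 (−0.27 to 0.43). The skeletal muscle denervation list had 9 genes higher and 12 lower (camera adjusted p = 0.572).

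No marker list of the resident cell types of the corpus cavernosum passed the list test, which with 3 rats per group does not show that they were unchanged. Smooth muscle contractile genes had 4 members higher and 10 lower, with a median log2 change of −0.01 (camera adjusted p = 0.555). Without CN resection rat 3 this list was lower at a camera adjusted p of 0.00514, with a mean log2 change of −0.24. Without both sham rat 2 and CN resection rat 3 it was lower by −0.23 (camera adjusted p = 0.00527). Both p-values rest on the preset inter-gene correlation of 0.01. The estimate over the 6 arrays was 0.44 for this list, so they may be far too small. With each gene centred over the 6 arrays, the list's median was −0.33 and −0.14 on CN resection arrays 1 and 2. It was −0.12 to 0.18 on the sham arrays and 0.27 on CN resection array 3. Tagln, Myl9 and Actg2, all contractile proteins, differed by −0.40, −0.31 and −0.28, and Des, the muscle intermediate filament, by −0.13 (−0.86 to 0.60). Endothelial markers had 8 members higher and 6 lower (camera adjusted p = 0.874); Kdr, a VEGF receptor read by a probe among the brightest 5%, differed by −0.33 ± 0.11 (SE). Fibroblast markers had 7 higher and 5 lower (camera adjusted p = 0.869). Skeletal muscle fibre genes had 7 higher and 16 lower (camera adjusted p = 0.196). This list was lower at an adjusted p of 0.00184 without sham rat 2, 0.00444 without CN resection rat 2, 0.00295 without both sham rat 2 and CN resection rat 3, and 0.00895 with array weights, where the mean log2 change was −0.35. Those p-values rest on the preset correlation too, while the estimate over the 6 arrays was 0.42 for skeletal muscle genes. Over all alternatives the list's adjusted p ran from 0.00184 to 0.967, and without CN resection rat 1 its mean log2 change was 0.10. These means include Tnnt1, which was not well above background on CN resection arrays 2 and 3; with probes above background on all 6 arrays the mean was −0.10 (adjusted p = 0.325). With each gene centred over the 6 arrays, the list's medians differed more between rats of a group than between the groups. They were 0.12, −0.24 and 0.16 on sham arrays 1 to 3, and −0.22, 0.28 and 0.12 on CN resection arrays 1 to 3. The highest and lowest lay 0.52 apart in log2, or 1.43-fold.

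Ribosomal protein and immediate early genes were higher as lists at the preset inter-gene correlation of 0.01. They did not pass with an estimated correlation, where no list had an adjusted p under 0.909. Of 32 measured ribosomal protein genes, 28 were higher and 4 lower, with a median log2 change of 0.29 over the 30 in the test (camera adjusted p = 0.00952; adjusted p = 0.909 with an estimated correlation). Their estimated correlation was 0.66, far above the preset value. Rplp1 and Rpl5 differed by 0.52 ± 0.30 (SE) and 0.35 ± 0.19, and no member passed over all genes or adjusted over the list alone. The list's median was lowest on sham array 2, at 0.82 against 1.37 to 1.88 on the other arrays, and highest on CN resection array 3. The call ended with array weights (adjusted p = 0.736), without sham rat 2 (mean log2 change 0.09, adjusted p = 0.730), without sham rat 3 (adjusted p = 0.141) and without CN resection rat 3 (adjusted p = 0.0584). Without both sham rat 2 and CN resection rat 3 the mean log2 change was 0.01 and camera placed the list lower than other genes (adjusted p = 0.472); over all alternatives the adjusted p ran from 9.88e-14 to 0.916.

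Immediate early genes, many of which encode transcription factors, are induced within minutes of a stimulus, handling of the tissue included. Of 17 measured, 15 were higher and 2 lower, with a median log2 change of 0.24 (camera adjusted p = 0.0133; adjusted p = 0.909 with an estimated correlation). The estimate was 0.21, against the preset 0.01. Fos was at −3.85 ± 0.46 (SD, n = 3) in sham rats and −2.84 ± 0.90 (SD, n = 3) after CN resection, and Nr4a3, Nr4a1 and Atf3 differed by 0.36, 0.48 and 0.36, none passing. The list's median was −1.51, −1.30 and −1.37 on sham arrays 1 to 3 and −1.05, −1.23 and −0.49 on CN resection arrays 1 to 3. This median is the level of the middle gene, Nr4a1 on every array but CN resection array 3. The separation of the groups is therefore close to that of 1 gene. Medians of the neurotrophic, inflammation and muscle denervation lists did not overlap between the groups either. The call ended with normexp (adjusted p = 0.0533), with array weights (adjusted p = 0.0813), and without sham rat 2 (adjusted p = 0.0653), CN resection rat 1 (adjusted p = 0.0526) or CN resection rat 3 (adjusted p = 0.0584), and over all alternatives the adjusted p ran from 4.73e-05 to 0.909. None of the 34 lists passed with fry, a test of whether a list's genes moved 1 way on balance, where the lowest adjusted p was 0.055.

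**Figure D3:**
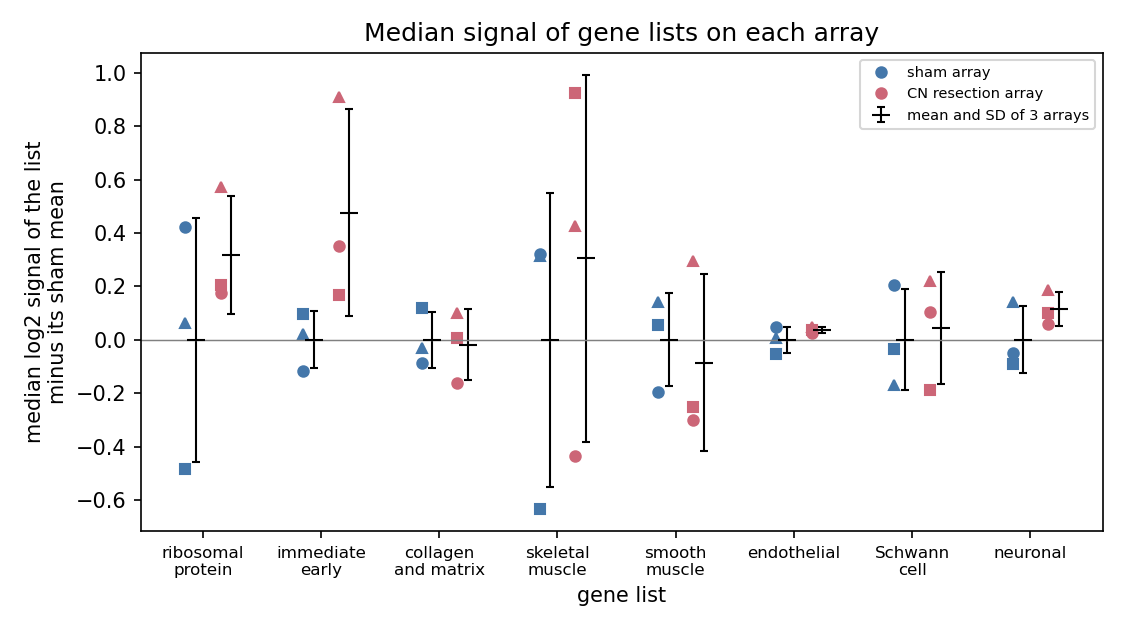
Median log2 signal of 8 gene lists on each array, set against the list's sham mean; blue points are sham arrays, red points CN resection arrays (circle, square and triangle for rats 1, 2 and 3), and black bars the mean and SD of 3 arrays. The groups do not overlap for immediate early genes, where the median is the level of Nr4a1 on every array but CN resection array 3. Skeletal muscle genes spread most as drawn, from −0.97 to 0.59 before the sham mean was subtracted. These are levels of different genes on different arrays. With each gene centred over the 6 arrays, their medians ran from −0.24 to 0.28, and those of ribosomal protein genes from −0.52 to 0.33.

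Since fewer than 5 genes passed in either direction, the 10 genes with the smallest p in each direction were named; none of them passed, at a limma adjusted p of 0.903 each. The 10 higher genes were Or10z1, Bclaf3, Smim26, Tdpozl1, Rnf152, Grm8, Elmod2, Gsta1, Mmp23 and Apoe. Apoe, the lipid carrier of macrophages and glia, was at −0.40 ± 0.29 (SD, n = 3) in sham rats and 0.44 ± 0.12 (SD, n = 3) after CN resection, a log2 difference of 0.84 (0.46 to 1.22). Gsta1, a glutathione transferase, differed by 0.81 (0.46 to 1.15), and Grm8, a glutamate receptor, by 0.60 (0.35 to 0.85). The 10 lower genes were Gpr182, Cox18, Vom2r36, Ptms, Prima1, Aqp12a, S100a5, Or13p5, Clec3a and Acaca, with log2 differences from −0.61 for Clec3a to −0.37 for Acaca, a fatty acid synthesis enzyme. Of these lower genes, 8 of the 10 were read by probes among the brightest 5%, and 0 of the 10 higher genes were. Probes of olfactory and vomeronasal receptors, a family of sensory neurons to which Or10z1, Vom2r36 and Or13p5 belong, were above background for 1022 of 1080 genes (94.6%, exact interval 93.1% to 95.9%), close to the 94.9% of other genes with a symbol, so a signal above background does not by itself show the named transcript.

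Above background on all 3 sham arrays and on no CN resection array were 3 genes, and 0 genes the other way round. Bounds were taken as the bright group's mean log2 signal against the higher of the dim array's own signal and the lowest signal well above background on it. By the means of these arrays Smc3, a cohesin subunit, was at least 1.25-fold higher in sham rats, Trpc4ap at least 1.26-fold and the unmatched accession DV718231 at least 1.35-fold (limma adjusted p = 0.903 for each). These bounds allow for the detection limit but not for the spread between rats. The unadjusted limma p was 0.088, 0.076 and 0.126. Of the 10 ways to split the 6 arrays into 3 and 3, 8 gave as many such genes, the real split included.

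The largest changes of single genes lay in 1 corner of CN resection array 3, where 23.3% of spots were marked as outliers against 1.00% elsewhere on it. Of the 50 genes with the largest change, 48 had their probe in that corner, and 48 were lowest on that array.

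**Figure D4:**
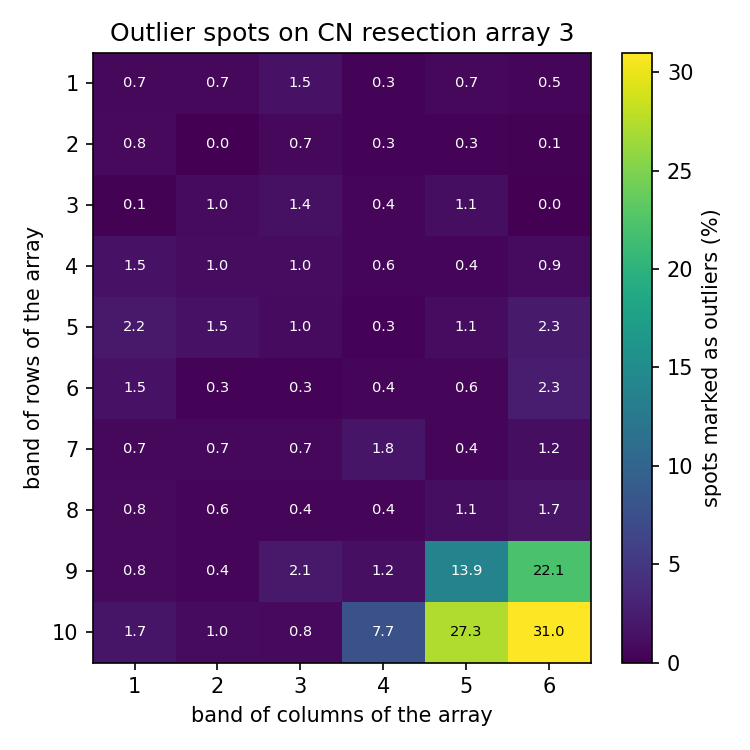
Percent of spots marked as outliers on CN resection array 3, over 60 blocks of the array (10 bands of rows by 6 bands of columns), with each block's percent printed in it. The blocks of the last rows and columns reach 31.0%.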

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

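Keeping marked spots, leaving out the corner of 1 array, leaving out both distant arrays and averaging the same probes were chosen after the results were seen; the other alternatives were planned. Slide could not be fitted as a block, because each slide held 1 group. Genes at an adjusted p under 0.05 were 0 under every alternative except the average of whichever probes had a value, which gave 7, where the probes averaged differed between arrays, and an unadjusted p under 0.05 with at least 2-fold, which gave 10 and has no adjustment. Genes at an unadjusted p under 0.05 were 1097 with median scaling, 2607 with array weights and 2832 without both distant arrays, and 1214 to 2008 leaving out 1 rat.

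Lists called were 1 with normexp, 2 with array weights (collagen and skeletal muscle, both lower; skeletal muscle mean −0.35, adjusted p = 0.00895), 0 with an estimated correlation, 0 with fry, 6 without both distant arrays (smooth muscle, skeletal muscle, collagen, hypoxia, macrophage and respiratory chain, all lower) and 1 to 3 leaving out 1 rat. The collagen mean log2 change was −0.047 with normexp (adjusted p = 0.0533), −0.0098 with quantile normalization (0.427) and −0.085 with the replicate block (0.0697), an estimated correlation (0.909) and fry (0.642); leaving out 1 rat it ran from −0.109 to −0.055. Immediate early genes had 0.27 with normexp (0.0533), 0.26 with array weights (0.0813), 0.22 without both distant arrays (0.343), and 0.28 with an estimated correlation (0.909) and fry (0.642); leaving out 1 rat gave 0.20 to 0.41. Ribosomal protein genes had 0.10 with array weights (0.736), 0.27 with an estimated correlation (0.909) and fry (0.916), and 0.091 to 0.47 leaving out 1 rat; without both distant arrays the mean was 0.0135 and the direction of camera reversed (0.472). The cause of these losses was not tested. Estimated inter-gene correlations were 0.66 for ribosomal protein, 0.21 for immediate early and 0.04 for collagen genes, all above the preset 0.01. Unadjusted camera p also rose where the estimate was below 0.01, from 0.078 to 0.125 for neurotrophic and 0.141 to 0.196 for mast cell genes. Among such lists only lymphocyte genes went the other way, from 0.791 to 0.789. The losses with an estimated correlation therefore need not come from the size of the estimates.

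Lists that did not pass stayed so in 704 comparisons and passed in 9. Named genes moved by less than their SE in 3494 comparisons and by more in 173, and the sign differed in 55 of 3667 gene and 81 of 782 list comparisons. The replicate numbers gave correlations of 0.01, 0.42 and 0.33 between same-numbered rats, and numbers 2 and 3 correlated best with their own. Number 1 stayed under 0.1, so the numbers were not taken to pair the rats. The replicate block gave 2098 genes at an unadjusted p under 0.05 and 2 lists. In 9 lists the median or mean differed in sign from the test, 0 of them passing. Signal over background limits the dim probes.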

Other observations

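The tests of the corner, of the skeletal muscle list, of collagen lists matched on brightness and of splits for genes above background in 1 group were chosen only after the result was seen.

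Inflammatory and stress pathways gave no call in the tissue 12 weeks after CN resection. Of 35 inflammation genes, 19 were higher and 16 lower (camera adjusted p = 0.874); Spp1, the secreted phosphoprotein osteopontin, had a log2 difference of −1.01 ± 0.23 (SE) and Cxcl1, a neutrophil chemokine, of 0.25, neither passing. Interferon and antigen presentation genes were higher for 20 of 27 (camera adjusted p = 0.555), with Mx2 at 0.31 and Cd74, the class II invariant chain, at 0.56. Apoptosis genes were lower for 21 of 32 (camera adjusted p = 0.315). In the oxidative stress list 19 genes were higher and 15 lower (camera adjusted p = 0.874), and Gsta1 passed adjusted over the list alone (adjusted p = 0.0381) but not over all genes. Hypoxia and angiogenesis genes had 13 higher and 14 lower (camera adjusted p = 0.746), with Ldha, a glycolytic enzyme, at −0.53, and respiratory chain genes 21 higher and 15 lower (camera adjusted p = 0.874). Androgen genes (11 higher, 6 lower; 0.869), cell cycle genes (10 higher, 7 lower; 0.874) and heat shock genes (5 higher, 11 lower; 0.414) did not pass by camera adjusted p.

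Markers of other cell types gave no call either. Macrophage genes had 6 higher and 12 lower (camera adjusted p = 0.572), with Fcgr2b, an Fc receptor, at 0.32. Lymphocyte genes had 9 higher and 10 lower (0.874), mast cell genes 5 higher and 7 lower (0.534), and red blood cell genes 4 higher and 5 lower (0.746). Squamous epithelial genes had 4 higher and 9 lower (0.572), urothelial genes 8 higher and 6 lower (0.874), adipocyte genes 10 higher and 9 lower (0.916), and cartilage and bone genes 6 higher and 9 lower (0.555). Krt14, a basal keratin, differed by −0.23 and was read by a probe among the brightest 5%.

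The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes at an adjusted p under 0.05 the real value was 0 and the highest other 0, so 10 of the 10 splits were as large. For genes at an unadjusted p under 0.05 the real value was 1707 and the highest other 3800, and 5 splits were as large; for lists the values were 3 and 5, with 3 splits as large. For genes above background in 1 group only they were 3 and 152, with 8 splits as large. The split with 3800 genes set sham rats 1 and 3 and CN resection rat 3 against the rest. It was picked as the highest after the counts were seen, so it does not show a structure of the samples.

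The brightest probes read lower on every CN resection array. Bright control spots, which do not depend on the rats' RNA, were at 3.78 ± 0.07 (SD, n = 3) on the sham slide and 3.4 ± 0.14 (SD, n = 3) on the CN resection slide, a log2 difference of −0.38, so a slide-wide difference in how bright spots read may account for it. Among probes, 24 were marked as outliers on all CN resection arrays and no sham array, each above brightness percentile 96.5, and 0 the other way. The collagen list's mean log2 change of −0.08 lay at percentile 10.9 of 10000 lists matched on brightness, whose central 95% ran from −0.13 to 0.04. A fall of collagen transcripts and the slide difference cannot be told apart, because each slide held 1 group.

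The largest single-gene changes sat in 1 corner of CN resection array 3. Of the 50 largest, 96.0% had their probe in that corner (exact interval 86.3% to 99.5%), against 6.40% of all genes, and 48 were lowest on that array. Their median absolute log2 change was 1.94 and 0.0689 without that array, which argues against a loss of these transcripts after CN resection. A damaged corner is a candidate explanation.

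Skeletal muscle genes differed between arrays more than other genes: the SD of the list's centred median over arrays was 0.21 against a median of 0.03 for 10000 matched random lists, at percentile 100. This restates the pattern and does not bear on its cause, so tissue pieces with differing amounts of skeletal muscle stay open as an explanation. The array-wide axis held 9.55% of the variance of the 22 members used (bootstrap 5.86% to 16.1%) against 55.6% over all genes. This argues against that axis as the whole cause of the list's spread. The members vary together, at an estimated correlation of 0.42, so they are not independent replicates. Between the groups lay 1.42% of the variance of the list's median. That share restates the medians given above. Most of their spread lay between rats of the same group, which a uniform effect of CN resection does not account for. The ranges over arrays were 20.1-fold for Myh4, 10.4-fold for Ckm and 9.35-fold for Myh1, while the bright members Tnni2 and Cox6a2 varied by 1.23-fold each. Tnnt1, a slow-fibre troponin, was well above background on the 3 sham arrays and on 1 CN resection array but not on CN resection arrays 2 and 3, so its range has only a bound, at least 7.19-fold, and it did not follow Myh4 and Ckm, which were highest on CN resection array 2.

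Spots for the E1A spike transcript were above background for 70.3% to 90.3% of spots on an array, and negative control spots for at most 1.96%. Over genes with 2 probes, the log2 differences of both had the same sign for 53.9%.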
